A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

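RNA was sequenced from 8 samples of 10-day-old rice seedlings (Oryza sativa Japonica Group, cultivar Dongjin) carrying GOS2:OsNF-YA5-GR, grown at 30 °C with 16 h of light and 8 h of darkness per day. Per the labels' protocols, the seedlings were treated with 50 µM dexamethasone (DEX) or mock, RNA was extracted from ground seedlings with an RNeasy kit, and libraries were made with a TruSeq stranded mRNA kit. The titles give 4 groups of 2 libraries: DEX at 3 h, mock at 3 h, DEX at 9 h and mock at 9 h. The labels do not say whether replicates came from separate batches of plants, so p-values measure the spread between these samples, which may be technical. Untransformed plants with DEX, and the time of day at harvest, are not given in the sources used here.

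The sources disagree about which libraries received DEX. The columns of the deposited series table carry names that match the sample titles, and samples were assigned to groups by those names. Each of the 8 sample records also holds a per-sample file, and the FPKM values in that file equalled those of the column named for the other treatment at the same time and replicate number in 100% of the genes above 1 FPKM in any library (tolerance 0.01), against at most 1.173% for the next best column. The names of these per-sample files carry that other treatment as well. The files thus go with the column names, and the sample records that hold them differ. Times and replicate numbers agree between both sources. Every direction given for DEX below is therefore provisional: it is the direction for the libraries whose columns are named DEX. An exchange of the names would turn all of these directions around and leave the number of genes called between DEX and mock as it is. The change with time in mock would then rest on the libraries now named DEX, and that comparison was not run.

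Per the submitters' processing notes, HISAT2, Bowtie2, StringTie and the IRGSP-1.0 genome were used, with the roles of the aligners and their versions not given in the sources used here. Per the file headers, StringTie 1.3.4d was run in its reverse-strand mode and restricted to the annotated transcripts of the 2013 annotation, 1 library at a time, so opposite-strand genes that overlap were counted by strand. The authors deposited estimated counts of reads per gene, made from StringTie coverage, already whole numbers and not normalized between libraries. These estimated counts equal the transcript coverage in the deposited per-sample files times the transcript length divided by a read length of 101 (the length that gave back the most counts), rounded up per transcript and summed per gene, for at least 99.786% of genes in each library. Because such counts are rebuilt from coverage, reads shared between near-identical paralogs were divided by the authors' tool, and levels of single members of a gene family are uncertain to that extent. The authors also deposited FPKM, scaled within each library to gene length and total fragments. The deposited table describes 37869 genes on 12 chromosomes, of which 35679 are protein-coding and 2190 are non-coding RNA, and no row lacked a gene name. Names and descriptions come from that table and positions from the authors' IRGSP-1.0 files. The gene name table given as a reference belongs to another assembly, its identifiers did not match, and it was not used.

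Total counts ranged from 32515938 to 47531536 per library, and 26708 to 28037 genes had at least 1 count. The 10 genes with the highest counts held 5.8 to 9.7% of a library. Among genes with a mean of at least 5 TMM-scaled CPM, 7.5 to 11.8% differed more than 2-fold between the replicates of a group.

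Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F-test). All 8 libraries entered 1 fit with a mean per group, which left 4 residual degrees of freedom and tested 25366 genes. The planned contrasts were DEX against mock at 3 h, DEX against mock at 9 h, the difference between these effects, and 9 h against 3 h in mock. P-values were adjusted by Benjamini-Hochberg and called at 0.05. Standard errors are those implied by the F statistic. CPM are TMM-scaled and given as mean ± SD with n = 2 per group unless another n is stated. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile scaling, no low-count filter, at least 1 CPM in 4 libraries, a minimum log2 fold change of 1, limma 3.58.1 with a trend on log2(TPM + 1) computed from the deposited FPKM for genes with a mean TPM of at least 1, fits of only the 4 libraries compared, leaving out each library, assigning columns by the per-sample file, and the replicate number as a block.

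The pairing by replicate number was checked before the blocked fits were compared. Deviations of same-numbered libraries from their group means correlated across genes with r between 0.376 and 0.596 over the 6 pairs of groups, 0.467 between DEX and mock at 3 h and 0.586 at 9 h, and the first principal component parted the replicate numbers. The numbers were therefore taken to pair the libraries. Between times the correlations spanned 0.376 to 0.596, so the check shows a difference common to all groups. It does not single out pairs of DEX and mock within a time. With 2 libraries per group the deviations within a group mirror each other.

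A comparison over both times was added after the planned comparisons of DEX with mock had called no gene. It was chosen after seeing the data. It fits 1 block for each pair of libraries of the same time and number, with 3 residual degrees of freedom. In all, 5 models of this pooled contrast were fitted, and the model reported is the one that called the most genes among those fitted with edgeR. The common biological coefficient of variation was 0.409 with group means alone, 0.255 with the replicate number as a block and 0.218 with a block per pair.

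The procedure was tested on simulated counts of 25366 genes with the means, library sizes and spread of these data. Known changes were placed only in genes with a mean of at least 5 CPM, so the recovery does not cover genes with lower counts. For the comparison at 3 h it recovered 1.5% of 2-fold, 38.8% of 4-fold and 97% of 16-fold changes, with 8 false calls. DESeq2 in the same simulation recovered 17.9% of 2-fold and 94% of 4-fold changes with 107 false calls. In the data at 3 h DESeq2 called 43 genes in all. The simulation at 3 h drew each library independently, with the spread of the group-means fit. It thus lacked the spread that same-numbered libraries share and cannot measure the false calls of DESeq2 in these data. Those stay unknown, so its larger counts are given but not relied on. With a low spread (a coefficient of variation of 0.1) at the same depth, the comparison at 3 h recovered 98.5% of 2-fold changes. The pooled fit recovered 79.1% of 2-fold changes with 19 false calls.

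Gene lists (30, of which 29 had nuclear members to test) were fixed by words in the descriptions and by identifiers before the data were examined. They were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and with an estimated correlation, each adjusted over the lists, and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. Sets needed at least 5 tested members, and tests of lists outside the comparisons at 3 h and 9 h were added after seeing the data. The list of organelle-encoded genes had no member in the table. By the rule fixed beforehand, a listed identifier that the table annotates as another kind of gene was to be dropped. As applied, only identifiers described as a non-protein coding transcript were dropped. Os10g0554200, described as a TGF-beta receptor family protein, was kept in the nitrate and ammonium transport list. The drop took out 1 member of the nitrogen assimilation list (Os01g0681900, described as a non-protein coding transcript). This was done after the list results had been seen and made that list's p smaller, so the value with it kept is given beside the result. Lists without members matched by a chance use of the words were an alternative chosen after seeing the data.

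Genes are named by a rule fixed before the data were examined: per DEX comparison, the 10 largest changes in each direction among called genes with a mean of at least 5 CPM, a description and both DEX libraries on the same side of both mock libraries, or the 5 with the smallest p as not passing where under 5 pass; up to 4 called members per list; and all NF-YA, nitrate transporter, nitrate reductase and glutamine synthetase genes. For the difference between times and for time in mock the 5 largest were taken. For the difference between times both pair differences at 9 h had to lie on the same side of both at 3 h, and for the pooled comparison, in place of groups that part, all 4 pair differences had to have the same sign. Genes at no more than 3 counts in every library of a group are given as counts with no fold change.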

Results

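Transcript levels were measured by stranded mRNA sequencing in 8 samples of rice seedlings. The plants carried OsNF-YA5, an A subunit of the NF-Y complex that binds CCAAT boxes in promoters, fused to the hormone-binding part of the glucocorticoid receptor (GR) and driven by the GOS2 promoter, which is active in most rice tissues. DEX is a steroid that lets GR fusion proteins enter the nucleus. The design compares 50 µM DEX with mock at 3 h and at 9 h, with 2 libraries in each of the 4 groups. Total counts were 47531536 and 37352748 for DEX at 3 h, 40371192 and 32515938 for mock at 3 h, 37738007 and 37678506 for DEX at 9 h, and 32780330 and 38254954 for mock at 9 h. The first principal component held 37.3% of the variance of log2 CPM and separated replicate 1 from replicate 2 in all 4 groups, and the second held 28.2% and separated 3 h from 9 h. On the third component, which held 9.5%, the 4 libraries named DEX lay between -49.29 and -4.38 and the 4 named mock between 5.56 and 54.01. The treatment names rest on the columns of the deposited series table. In all 8 samples the sample record holds the per-sample file of the other treatment. "DEX" below therefore means the libraries named DEX in that table, and each direction is provisional.

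**Figure D1:**
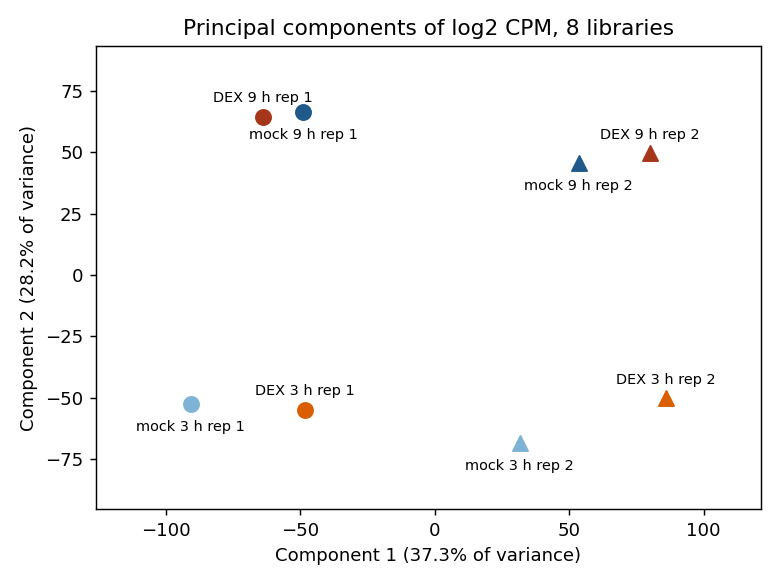
Principal components of log2 CPM over 25366 genes, with 1 point per library (circles for replicate 1, triangles for replicate 2, colours for the 4 groups) and each axis labelled with its share of variance. Replicate 1 lies left and replicate 2 right on component 1 (37.3%), and 3 h lies below 9 h on component 2 (28.2%).

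The first comparison asked which transcripts differed between DEX and mock 3 h after treatment. The genes with the smallest p were higher in both DEX libraries than in both mock libraries for a sterol methyltransferase, an F-box protein, a B-type response regulator of cytokinin signalling, a family 1 glycoside hydrolase and a DUF620 protein, and lower for a polygalacturonase inhibitor and a pyruvate, phosphate dikinase, but no gene passed the adjusted threshold. The sterol methyltransferase gene Os07g0206700 (chromosome 7, 5750899 to 5756651, 14 exons) stood at 134 ± 8.31 CPM with DEX and 62.6 ± 1.39 CPM with mock, a log2 fold change of 1.09 ± 0.19 (SE). The response regulator Os01g0904700 (chromosome 1, 39387278 to 39391014) stood at 56.4 ± 0.957 against 19.8 ± 1.14 CPM, the F-box gene Os08g0150700 at 11.5 ± 3.06 against 4.04 ± 0.653 CPM, and the DUF620 gene Os03g0267500 at 26.4 ± 6.09 against 12.5 ± 1.59 CPM. The glycoside hydrolase gene Os01g0897600 had a log2 fold change of 1.7 ± 0.32. The polygalacturonase inhibitor 1 gene Os07g0568700 (chromosome 7, 22874257 to 22875705, a single exon), whose product restrains pectin-degrading enzymes, stood at 11 ± 0.0257 CPM with DEX and 39.3 ± 0.17 CPM with mock (log2 fold change -1.83 ± 0.2). Os03g0432100, similar to pyruvate, phosphate dikinase 2 (chromosome 3, 18153151 to 18160127, 18 exons), which regenerates phosphoenolpyruvate from pyruvate, stood at 6.99 ± 0.938 against 28.7 ± 1.17 CPM (log2 fold change -2.03 ± 0.25). The DUF547 gene Os08g0476100 (log2 fold change -1.5), Os04g0412500 (-1.2) and the HAD hydrolase gene Os09g0388400 (-1.49) completed the 5 lowest p on that side. The edgeR quasi-likelihood test called 0 of 25366 genes at 3 h, with 568 genes at an unadjusted p under 0.05, and DESeq2 called 35 higher and 8 lower. The 568 genes are a smaller share than the 0.05 that would fall there with no effect. The group-means fit counts the difference between replicate numbers, which DEX and mock share, as spread. Its p-values tend to be too large for that reason, so the small share is no evidence that DEX had no effect. With the replicate number as a block edgeR also called 0, with 1655 genes at an unadjusted p under 0.05.

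Among the gene lists at 3 h, 5 passed camera with a preset correlation and none with an estimated one. Nitrogen assimilation genes ranked lower with DEX, with 20 of 30 tested members below 0 (median log2 fold change -0.19, camera adjusted p = 0.00489). That list's adjusted p was 0.0282 with the dropped identifier kept, 0.0402 without members matched by chance and 0.697 with an estimated correlation. Cytosolic ribosomal protein genes ranked higher, 149 of 174 above 0 with a median of only 0.10 (adjusted p = 0.000939, and 0.99 with an estimated correlation). Light-harvesting and photosystem genes (38 of 46 below 0, median -0.18) and cyclins and mitosis genes (24 of 31 below 0, median -0.18) ranked lower and peroxidases and glutathione transferases ranked higher (51 of 83 above 0, median 0.24), each at an adjusted p = 0.0402. With an estimated correlation these adjusted p were 0.99, 0.697 and 0.99. These calls changed when single libraries were left out. Fits without 1 of the libraries compared had no replicate block and set 1 replicate number against both, so differences between replicates enter them. At 3 h replicate 2 was higher by medians of 1.25 in DEX and 0.99 in mock for defence proteins. For peroxidases and glutathione transferases these medians were 0.71 and 0.79. The changes below therefore cannot be told apart from such differences. Without replicate 1 of mock at 3 h none of the 5 lists held, and peroxidases and glutathione transferases turned to the lower side. Without replicate 2 of DEX at 3 h light harvesting (0.458), cyclins (0.448) and peroxidases and glutathione transferases (0.962) were lost, without replicate 2 of mock at 3 h light harvesting (0.0667) and cyclins (0.112), and without replicate 1 of DEX at 3 h ribosomal proteins (0.428). Other lists passed only with a library left out, and not always on the same side, and with an estimated correlation each list that passed with a library left out, at 3 h or at 9 h, had an adjusted p from 0.676 to 0.979: defence proteins ranked higher without replicate 1 of DEX at 3 h (0.00456) and lower without replicate 2 (0.00573). Without that replicate 2, phytoalexins (2.78e-06), jasmonate (0.000138) and abscisic acid genes (0.00129) ranked lower. Without replicate 2 of mock at 3 h, abscisic acid genes ranked lower and auxin, WRKY and cell wall genes higher (each 0.0018). The cell wall list also ranked higher without replicate 1 of DEX at 3 h (0.00187), WRKY factors did so too (0.0455), and cell wall genes or root-enriched markers passed without single 9 h libraries (0.0181 to 0.0499). By fry no list passed at 3 h with all libraries. With the replicate block, cyclins no longer passed (adjusted p = 0.058) while cell wall loosening and synthesis (0.0114) and Calvin cycle genes (0.0427) did, with adjusted p = 0.923 and 0.604 with an estimated correlation. The other 24 lists, covering nitrate and ammonium transport, NF-Y subunits, the Calvin cycle and photorespiration, chlorophyll biosynthesis and breakdown, the circadian clock, abscisic acid, jasmonate, ethylene, auxin, cytokinin and gibberellin genes, heat shock, histones and replication, WRKY factors, defence proteins, diterpenoid phytoalexins, the cell wall, starch and sugar, phosphate, iron, aquaporins, and root and seed markers, had adjusted p from 0.0553 to 0.988. The phytoalexin list had a positive median (0.35) but ranked lower in the test, and the nitrate and ammonium transport, ethylene, cytokinin, gibberellin, heat shock and histone lists had negative medians but ranked higher. Replicates differed strongly in the phytoalexin genes, with a median log2 difference of 5.11 between those of DEX at 3 h. No list member passed the threshold over all genes. Adjusted over the list alone, 1 of 10 NF-Y subunits (Os03g0696300) and 1 of 7 root-enriched markers, the root cap family gene Os04g0410400 at 0.43 to 0.56 CPM in mock and 1.5 to 1.85 CPM in DEX libraries, were higher. With the replicate block the lipoxygenase genes Os08g0508800 and Os03g0700700, the DREB1F-like gene Os04g0549700 and the sucrose synthase gene Os02g0831500 were higher as well.

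The NF-YA and nitrogen genes were examined at both times whatever their test. Os03g0696300, an NF-YA gene similar to nuclear transcription factor Y subunit A-1 (chromosome 3, 27890692 to 27894467, up to 7 exons), stood at 105 ± 1.01 CPM with DEX and 57.0 ± 0.756 CPM with mock at 3 h (log2 fold change 0.89 ± 0.18), and at 76.7 ± 15.9 against 43.4 ± 1.78 CPM at 9 h (0.82 ± 0.18). Os07g0158500 had the highest level of the NF-YA genes, at 233 ± 26.7 CPM with DEX and 289 ± 36.7 CPM with mock at 3 h and 183 ± 43.6 against 208 ± 0.329 CPM at 9 h. The other 6 NF-YA genes tested had log2 fold changes from -0.37 to 0.43 at 3 h and from -0.62 to 0.28 at 9 h. The files do not pair the name NF-YA5 with an identifier. Nitrate reductase, which reduces nitrate to nitrite, was read from Os08g0468100 (chromosome 8, 23033230 to 23038585), at 264 ± 56.8 against 466 ± 52 CPM at 3 h and 33.7 ± 15.1 against 65.6 ± 4.74 CPM at 9 h, and from Os08g0468700, at 140 ± 13.8 against 237 ± 22 CPM and 39.6 ± 5.6 against 55.1 ± 4.5 CPM. A further gene, Os02g0770800, varied widely between replicates. The ferredoxin-nitrite reductase gene Os01g0357100 (chromosome 1, 14446913 to 14453454), chosen after its values were seen, stood at 837 ± 85.8 against 1480 ± 416 CPM at 3 h and 512 ± 69.1 against 714 ± 13.9 CPM at 9 h. Of the glutamine synthetase genes, the root isozyme Os03g0223400 was at 34.8 ± 4.2 against 65.1 ± 33.8 CPM at 3 h, and the other 3 with a fold change lay between -0.21 and 0.17 on the log2 scale. The 11 nitrate transporter genes with a fold change ranged from -1.02 to 0.85 at 3 h and from -0.77 to 0.57 at 9 h. They include Os10g0554200, which was listed by its identifier and is described as a TGF-beta receptor family protein. None of these genes passed the adjusted threshold of edgeR at either time.

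**Figure D2:**
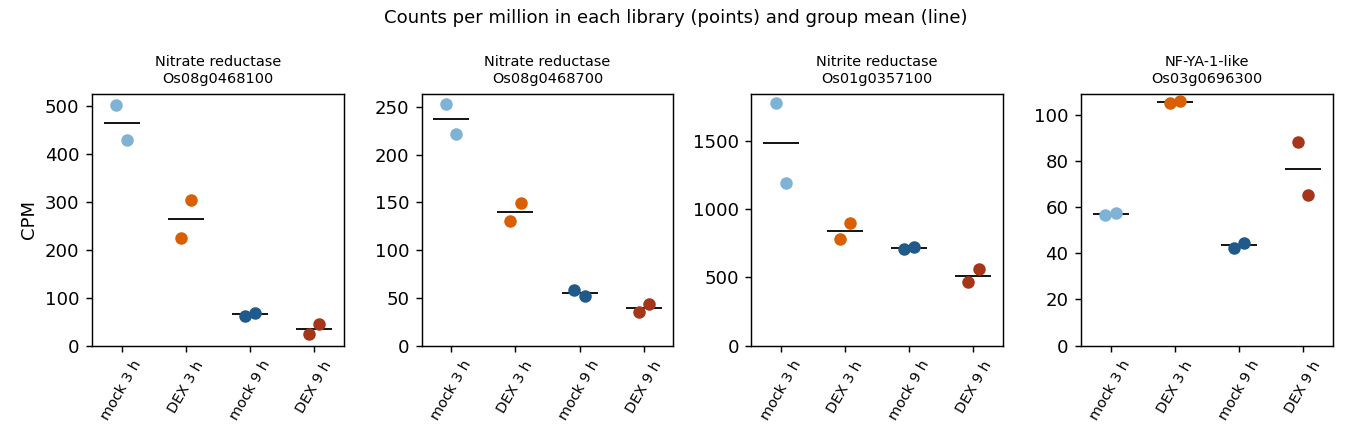
CPM (y axis) in each library (points) and group means (lines) of 2 nitrate reductase genes, a nitrite reductase gene and the NF-YA gene Os03g0696300, by group. At 3 h the DEX points of the reductases lie below the mock points, with means of 264 against 466 for Os08g0468100, and those of Os03g0696300 lie above, with means of 105 against 57.0.

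The same question was asked 9 h after treatment. The smallest p belonged to Os06g0697500, an AAA-type ATPase (chromosome 6, 29180264 to 29181822), at 9.26 ± 0.63 CPM with DEX and 1.62 ± 0.0559 CPM with mock, a log2 fold change of 2.52 ± 0.32. Os10g0344000, similar to the multidrug and toxin extrusion transporter transparent testa 12, stood at 23.9 ± 3.67 against 5.65 ± 0.873 CPM, and the homeobox-associated gene Os12g0160500 at 38.0 ± 6.49 against 18.3 ± 1.63 CPM. The F-box gene Os08g0150700 (log2 fold change 1.85) and the DUF620 gene Os03g0267500 (1.21) were again among the 5 with the smallest p. On the lower side, Os03g0432100, similar to pyruvate, phosphate dikinase 2, stood at 9.79 ± 1.93 against 27.4 ± 6.53 CPM (-1.49 ± 0.25), the sulphate transporter gene Os04g0652400 at 29.8 ± 3.8 against 89.0 ± 42.6 CPM, and the AUX/IAA gene Os08g0109400, of a family of auxin response repressors, at 17.7 ± 1.56 against 33.6 ± 6.14 CPM. The subtilase gene Os01g0795000 (-1.0) and Os07g0568700 (-0.81) followed. The edgeR test called 0 genes at 9 h, with 504 at an unadjusted p under 0.05, again a smaller share than 0.05. With the replicate number as a block 1173 genes lay there and 0 were called. DESeq2 called 35 higher and 4 lower, limma on log2(TPM + 1) called 1, the 40S ribosomal protein S18 gene Os07g0173700, and edgeR without replicate 1 of DEX at 9 h called 1, the helix-loop-helix gene Os01g0924400.

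At 9 h, 2 lists passed camera with the preset correlation. Cytosolic ribosomal protein genes again ranked higher (149 of 174 above 0, median 0.13, adjusted p = 6.39e-08, and 0.949 with an estimated correlation), and this call was lost without replicate 1 of DEX (0.636) or replicate 2 of mock (0.243) at 9 h. Nitrogen assimilation genes ranked lower, with 22 of 30 below 0 and a median of -0.22 (adjusted p = 0.0305). That list's adjusted p was 0.0468 with the dropped identifier kept, 0.0935 without members matched by chance and 0.859 with an estimated correlation. It was 0.455 without replicate 1 of DEX at 9 h, 0.36 without replicate 2 of mock at 9 h, and 0.0762 and 0.0969 without replicates 1 and 2 of DEX at 3 h. By fry no list passed at 9 h. As at 3 h, fits without 1 of the libraries compared had no replicate block, so differences between replicates enter them. Other lists passed at 9 h only with a library left out: defence proteins (6.17e-05), cell wall (0.000417) and iron genes (0.0275) as lower without replicate 2 of DEX, and WRKY factors (0.0131) and peroxidases and glutathione transferases (0.00309) as higher without replicate 1. Without replicate 2 of mock at 9 h the latter 2 lists (each 0.0167) and phytoalexins (0.0296) ranked higher, and without replicate 1 light harvesting ranked higher (0.0399) and defence proteins lower (0.0421). The other 27 lists had adjusted p from 0.0866 to 0.9. Median and test differed in sign at 9 h for NF-Y subunits, light harvesting, chlorophyll breakdown, ethylene, the cell wall and phosphate. Adjusted over the list alone, Os03g0696300 of the NF-Y subunits and the cytokinin dehydrogenase 2 gene Os01g0197700 (14.0 and 18.6 CPM with DEX, 4.97 and 6.86 CPM with mock) were higher at 9 h. With the replicate block so were the NF-YC gene Os06g0667100, the alpha/beta hydrolase gene Os11g0240600 of the gibberellin list and the glutathione S-transferase gene Os01g0692100. Of genes with almost no reads, the NRT2.7-like gene Os01g0547600 had 2 and 0 counts with DEX and 0 and 0 with mock at 9 h, and 23 and 26 against 3 and 10 at 3 h. The glutamine synthetase gene Os03g0712800 had 6 and 12 counts with DEX and 0 and 0 with mock at 9 h, and 2 and 16 against 26 and 6 at 3 h.

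Whether the difference between DEX and mock changed from 3 h to 9 h was tested as an interaction. Os04g0493600, similar to a chitin-binding lectin precursor, had the smallest p on the negative side, with DEX minus mock log2 differences of 1.97 and 2.14 in the pairs at 3 h and -1.79 and 0.31 at 9 h, followed by the neighbouring chitinase gene Os04g0493400 (0.58 and 0.93, then -1.03 and -0.32). Os04g0412900, a Sec23/Sec24-type gene, the beta-amylase gene Os07g0543300 and the DUF724 gene Os11g0302800 completed that side. On the positive side stood the polygalacturonase inhibitor Os07g0568700 (-1.82 and -1.84, then -0.9 and -0.74), Os01g0854000, similar to AER, Os03g0237100, similar to a codeinone reductase, the ammonium transporter gene Os05g0468700 (-0.21 and -0.3, then 0.45 and 0.23), and the alpha/beta hydrolase gene Os01g0557100. The edgeR test called 0 genes, with 138 (also a smaller share than 0.05) at an unadjusted p under 0.05. With the replicate number as a block 462 genes lay there, still a smaller share, and 0 were called. DESeq2 called 1, the iron-stress related gene Os02g0599500. That gene stood at 10.9 and 10.4 CPM in DEX at 3 h and at 11 CPM in replicate 2 of mock at 9 h and had no counts in the other 5 libraries, so its fold change is not given. Without replicate 1 of DEX at 9 h edgeR called 1, Os01g0924400. Across genes, which are not independent replicates, the fold changes at 3 h and 9 h correlated with r = 0.322. By pair, the 9 h difference of replicate 2 correlated with those at 3 h with r = 0.264 and 0.335. The 9 h difference of replicate 1 did so with only 0.058 and 0.035. Both pairs of the same time correlated with r = 0.111 at 3 h and 0.109 at 9 h. No calls overlapped between the times with edgeR. With DESeq2, 16 higher genes were shared between lists of 35 and 34, where independent lists would share 0.0498 (one-sided Fisher exact p = 1.62e-38), and 1 lower gene was shared. Both DESeq2 lists come from 1 fit with 1 estimate of spread per gene, so they are not independent and this p cannot serve as evidence. Of the gene lists, cell wall loosening and synthesis passed for this difference, with 61 of 87 members below 0 and a median of -0.49 (camera adjusted p = 0.00401, and 0.995 with an estimated correlation). The other 28 lists had adjusted p from 0.131 to 0.983, with median and test opposite in sign for nitrate and ammonium transport, NF-Y subunits, chlorophyll biosynthesis, gibberellin, WRKY factors and phytoalexins. With the replicate block, light harvesting (0.0343) and the diterpenoid phytoalexins (0.00229) also passed, each with an adjusted p = 0.998 with an estimated correlation, and the phytoalexin median turned from -0.24 to 1.35. Adjusted over the list alone, the cytokinin dehydrogenase gene Os01g0197700 passed with that block (1.18).

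Time in mock served as the background for both DEX comparisons. It compares the libraries named mock, which would be the DEX libraries if the names were exchanged. Between 3 h and 9 h of mock a chlorophyll-binding gene of the light-harvesting apparatus fell and a clock transcription factor rose. The LHY-like gene Os04g0583900 (chromosome 4, 29500955 to 29503774, 6 exons), a MYB factor of the circadian clock, rose from 0.923 ± 0.65 to 125 ± 73.1 CPM (log2 fold change 7.06 ± 0.78, edgeR adjusted p = 0.0447). The xyloglucan endotransglucosylase gene Os04g0604300, which remodels cell walls, rose from 1.26 ± 0.143 to 26.9 ± 6.71 CPM (4.42 ± 0.37, adjusted p = 0.0358). The phosphodiesterase-like gene Os02g0588500 (3.08), the B-box gene Os02g0646200 (3.05) and the cellulose synthase-like gene CSLC9, Os03g0770800 (2.93), also rose. The chlorophyll a/b-binding gene Os02g0197600 (chromosome 2, 5468648 to 5470490, 4 exons) fell from 2280 ± 130 to 41.1 ± 10.5 CPM (-5.79 ± 0.6, adjusted p = 0.0435). A different B-box gene, Os08g0249000 (-5.95), the CONSTANS-like gene Os03g0711100 (-4.53), the malate dehydrogenase gene Os07g0630800 (-4.21) and the Dof gene Os07g0685000 (-4.15) also fell. In total 8 genes rose and 41 fell, among them the nitrate reductase gene Os08g0468700 (log2 fold change -2.11). The count was 816 with the replicate block (297 higher and 519 lower, including all 49), 1224 with DESeq2, 0 in a fit of only the 4 mock libraries, 8 without replicate 1 of mock at 3 h and 0 without any other library.

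**Figure D3:**
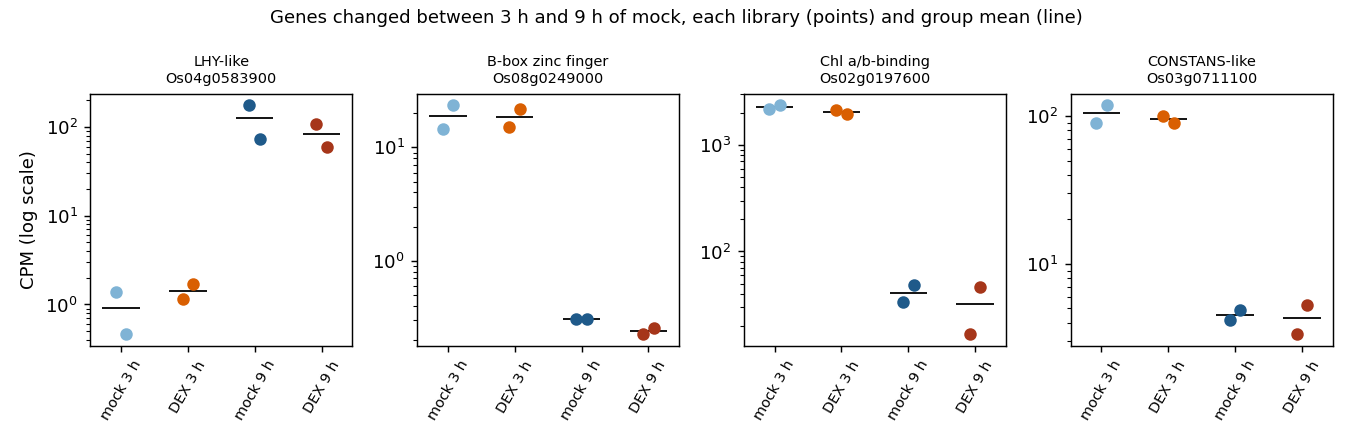
CPM on a log scale (y axis) in each library (points) and group means (lines) of 4 genes that changed between 3 h and 9 h of mock, by group. The LHY-like gene lies near 1 CPM at 3 h and above 50 CPM at 9 h, and the other 3 genes are lower at 9 h than at 3 h in both treatments.

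By list, light-harvesting and photosystem genes ranked lower at 9 h of mock, with 38 of 46 members below 0, a median of -1.15 and 4 called lower over all genes (23 lower and 1 higher adjusted over the list alone, camera adjusted p = 6.26e-17, and 0.284 with an estimated correlation). Chlorophyll biosynthesis genes ranked lower as well (10 of 13, median -0.35, 2 called, adjusted p = 0.000252, and 0.284 with an estimated correlation), as did heat shock genes and chaperones (84 of 145, median -0.21, adjusted p = 0.00145, and 0.406 with an estimated correlation). Cytosolic ribosomal protein genes (151 of 174 above 0, median 0.19, adjusted p = 1.64e-05) and histone and DNA replication genes (33 of 49 above 0, median 0.35, adjusted p = 0.00532) ranked higher. With an estimated correlation these last adjusted p were 0.807 and 0.472. By fry, light harvesting and chlorophyll biosynthesis (each adjusted p = 0.0163) and the 6 cytokinin genes (0.039) passed as lower. With the replicate block chlorophyll biosynthesis no longer passed fry (0.0513) and heat shock did (0.0242). By camera with that block, jasmonate (0.0159) and cytokinin genes (0.0375) also passed, each with an adjusted p = 0.511 with an estimated correlation. The other 24 lists had adjusted p from 0.0938 to 0.969, and the circadian clock list had 0.736. Median and test were opposite in sign for the clock, defence, phytoalexin, starch and sugar, phosphate and seed marker lists.

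A comparison of DEX with mock over both times, with each pair of libraries of the same time and replicate number as a block, was added after the comparisons at each time had called no gene. In this fit 63 genes rose and 25 fell with DEX. With the names exchanged 25 would rise and 63 fall, and each direction below would turn. The largest rise with a described gene was in Os01g0627800, similar to the cytochrome P450 CYP72A5 (chromosome 1, 25060764 to 25063562, 5 exons), at 28.5 ± 13 CPM with DEX and 3.22 ± 1.76 CPM with mock (SD, n = 4; log2 fold change 3.18 ± 0.24, edgeR adjusted p = 0.0206). The O-methyltransferase gene Os12g0441600 (2.44), the glutathione S-transferase gene Os01g0692100 (2.32), the cysteine synthase gene Os02g0222100 (2.06), Os02g0575700 (1.96), the DUF3049 gene Os03g0705800 (1.9), the CYP78A9-like gene Os09g0528700 (1.73), the F-box gene Os08g0150700 (1.67), the transposase-like gene Os04g0629600 (1.67) and the pyridine nucleotide-disulphide oxidoreductase gene Os07g0564500 (1.61) also rose. Os03g0432100, similar to pyruvate, phosphate dikinase 2, fell from 28 ± 3.9 to 8.39 ± 2.03 CPM (-1.76 ± 0.14, adjusted p = 0.0206), and the sulphate transporter gene Os04g0652400 fell from 76.9 ± 28.5 to 27.3 ± 5.11 CPM (-1.45 ± 0.14, adjusted p = 0.0292). The heavy metal transport gene Os10g0209700 (-1.31), the leucine-rich repeat gene Os08g0247600 (-1.29), the cytochrome P450 gene Os07g0482900 (-1.24), the antiporter gene Os01g0279400 (-1.22), the polygalacturonase beta subunit gene Os10g0409400 (-1.18), the alpha-expansin OsEXPA2 gene Os01g0823100 (-1.12), the beta-glucanase gene Os05g0375400 (-1.04) and the extensin-domain gene Os03g0342100 (-1.03) also fell.

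**Figure D4:**
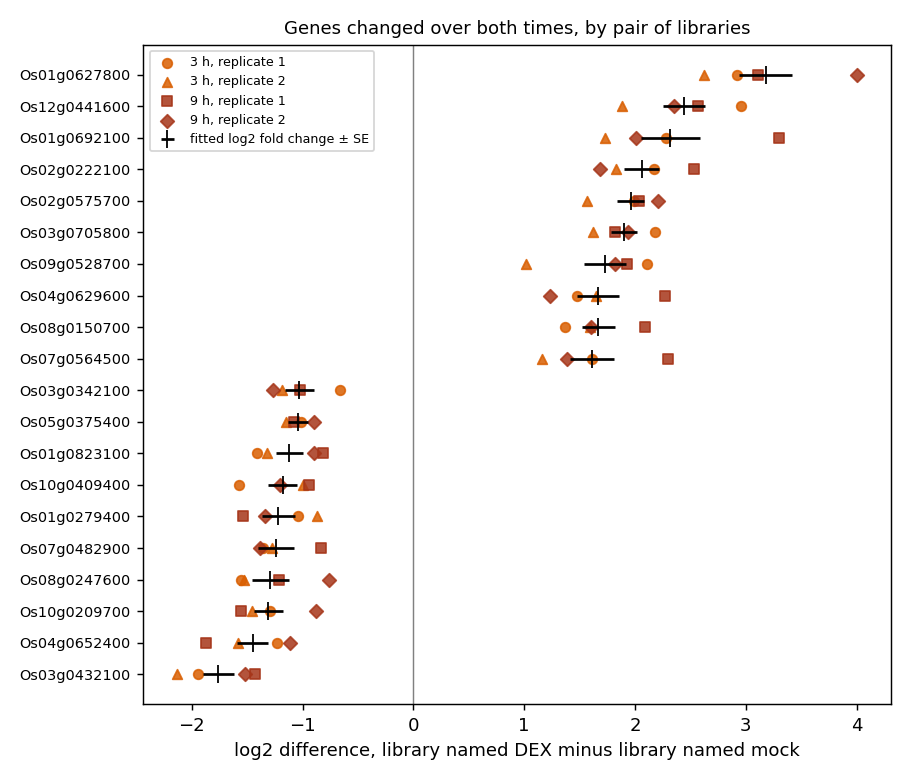
Log2 difference of the library named DEX minus the library named mock (x axis) in each of the 4 pairs of libraries (symbols) for the 10 largest described rises and falls over both times (y axis), with the fitted log2 fold change and its SE in black. All 4 pairs lie on the same side of 0 for each gene, as the rule for naming these genes required, from above 2 for Os01g0627800 to below -1 for Os03g0432100.

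Of 83 peroxidases and glutathione transferases, 3 rose (Os01g0692100, Os10g0530900 at 0.79 and Os01g0369700 at 0.84, all glutathione S-transferases) and the peroxidase gene Os10g0109600 fell (-0.88). The NF-YA gene Os03g0696300 rose (0.85 ± 0.1, edgeR adjusted p = 0.0455), as did the lipoxygenase gene Os08g0508800 (0.92), which acts in jasmonate synthesis, and the chitinase gene Os01g0860500 (1.59). Of 87 cell wall genes OsEXPA2 and OsEXPA4 (Os05g0477600, -1.03) fell, while 51 lay above 0 and the list did not pass (adjusted p = 0.756). WRKY30 (Os08g0499300, -0.81) fell. By camera, nitrogen assimilation (20 of 30 below 0, 1 called, the N-acetyl-glutamate synthase gene Os03g0431200, which the words matched by chance, 11 adjusted over the list alone, adjusted p = 0.00493, and 0.0145 with the dropped identifier kept; without members matched by chance 0 called, 8 adjusted over the list alone, 0.0248) and Calvin cycle genes (13 of 15 below 0, 0.0178) ranked lower, with adjusted p = 0.388 and 0.438 with an estimated correlation. Ribosomal proteins (156 of 174 above 0, 2.55e-08), peroxidases and glutathione transferases (55 of 83, 0.0178) and WRKY factors (47 of 78, 0.0478) ranked higher. With an estimated correlation these adjusted p were 0.952, 0.388 and 0.475. By fry, only nitrogen assimilation passed (adjusted p = 0.029, 0.0551 with the dropped identifier kept and 0.0938 without members matched by chance). The other 24 lists had camera adjusted p from 0.102 to 0.952, with median and test opposite in sign for nitrate and ammonium transport, cytokinin, phytoalexins and starch and sugar. The count of 88 genes depends on the model and on single pairs: it was 0 without a block, 4 with group means and the replicate block, 22 with time and replicate as separate terms and 1049 with DESeq2. It was 53 without the 3 h pair of replicate 1, 20 without the 3 h pair of replicate 2, and 0 without either 9 h pair.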

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

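All tests in this part were chosen after the result they bear on was seen. The cell wall loosening and synthesis list drew attention because its DEX minus mock difference was not alike at the 2 times. Its members had a median log2 fold change of 0.43 at 3 h, with 59 of 87 above 0, and of 0.03 at 9 h, with 46 of 87 above 0, and camera gave an adjusted p of 0.00401 for the difference with a preset correlation. Both medians moved when 1 library was left out. The 3 h median was -0.009 without replicate 2 of DEX and 0.159 without replicate 1 of mock. The 9 h median was -0.63 without replicate 2 of DEX. These fits had no replicate block and set 1 replicate number against both. The list was higher in replicate 2 by medians of 0.68 in DEX and 0.86 in mock at 3 h, and 0.61 and 0.25 at 9 h. The moves therefore cannot be told apart from the difference between replicates. The unadjusted p with an estimated correlation was 0.252, so the difference does not hold when members are allowed to vary together as they do in these libraries. No technical or biological explanation was tested for it.

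The pattern weighed here is the group of 88 genes called over both times. Of the 32 splits of the 8 libraries that the model can fit, 1 gave as many calls, the real one, and the highest other gave 2, but most of these part only 2 pairs and so rest on fewer pairs, and they decide nothing. Among the 8 splits that part all 4 pairs, as the real one does, 1 gave 88 and the highest other gave 0, and 8 splits are too few for a share under 0.05. Genes at least 2-fold apart in the same direction in all 4 pairs numbered 119 for the real assignment and up to 70 for the other 7. Library size is argued against, since thinning every library to the smallest total gave 104 genes, including all 88. What stays open is the direction, because all 8 sample records hold the values of the other treatment's column. No mark of DEX that is independent of the names was used here. An effect of DEX itself also stays open, because 0 libraries of plants without the transgene were analysed here. Chance stays open as well, because 8 splits are too few and the model was picked as the edgeR one with the most calls. If the changes do follow DEX, they could come from the NF-YA5 fusion protein or from the steroid, and these cannot be told apart.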

How the results depend on the processing

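Pooled models, leaving out pairs, thinning, lists without chance matches and the list with its dropped identifier kept were chosen after seeing the data, and all other alternatives were fixed beforehand. At 3 h and 9 h the count of 0 genes held with edgeR under RLE and upper-quartile scaling, both filters, a minimum log2 fold change of 1, the replicate block and fits of only the 4 libraries compared. DESeq2 gave 43 genes at 3 h, 39 at 9 h, 1 for the difference between times, 17 shared between times and 1224 for time in mock, and limma on TPM gave 1 at 9 h. Leaving out 1 library gave 0 to 1 genes at 9 h and for the difference, and 0 to 8 for time. Time in mock gave 90 genes without the low-count filter, 816 with the replicate block, 101 with limma on TPM and 0 in only the 4 libraries compared, which has fewer samples. DEX over both times gave 0 genes with no block, 4 with 4 group means and the replicate block, 22 with time and replicate block as separate terms, 1049 with DESeq2, 53 and 20 without the 3 h pairs of replicates 1 and 2, and 0 without either 9 h pair, which leaves 3 pairs. The 5 lists called at 3 h became 0 with an estimated correlation and 0 to 7 when 1 library was left out, and the 2 called at 9 h became 0 with an estimated correlation, 1 without chance matches and 1 to 5 when 1 library was left out. The replicate block changed no call over all genes at 3 h, 9 h or their difference. Counted over single genes and alternatives other than exchanged names, 586 results at 3 h and 595 at 9 h kept their direction and side of the threshold and 11 and 6 passed it, all with DESeq2. The direction turned in 27 results at 3 h and 23 at 9 h. For genes named over both times 83 held and 178 lost the threshold, and for time in mock 73 held and 87 lost it. Where a group is left with 1 library, that library is assumed to vary like the other groups. At this depth a simulated low spread gave 98.5% of 2-fold changes against 1.5% with the spread of these data. In the simulation the spread thus limited the calls among genes with a mean of at least 5 CPM. The simulation left out the spread that same-numbered libraries share, so how far this limit holds in these data was not tested. Depth was not varied in the simulation, so its part was not tested.

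The assignment by per-sample file gives each column the title of the sample record that holds its values. It exchanges DEX and mock by construction and turns every DEX direction around. At 3 h the log2 fold changes become -1.09 (Os07g0206700), -1.51 (Os08g0150700), -1.51 (Os01g0904700), -1.7 (Os01g0897600), -1.08 (Os03g0267500), 1.83 (Os07g0568700), 2.03 (Os03g0432100), 1.5 (Os08g0476100), 1.2 (Os04g0412500), 1.49 (Os09g0388400), 0.31 (Os07g0158500), 0.07 (Os08g0196700), 0.37 (Os10g0397900), -0.17 (Os03g0411100), 0.01 (Os07g0608200), 0.17 (Os12g0613000), -0.89 (Os03g0696300), -0.43 (Os02g0776400), 0.04 (Os03g0103000), -0.31 (Os10g0110800), 0.26 (Os10g0111300), -0.85 (Os08g0155400), -0.10 (Os03g0235900), 0.12 (Os10g0370700), 0.80 (Os04g0480200), -0.21 (Os10g0554200), -0.25 (Os06g0581000), -0.38 (Os03g0687000), 1.02 (Os01g0704100), 0.82 (Os08g0468100), 0.77 (Os08g0468700), 1.56 (Os02g0770800), 0.91 (Os03g0223400), -0.17 (Os10g0456500), 0.21 (Os04g0659100), -0.03 (Os02g0735200), 0.82 (Os01g0357100), 0.88 (Os01g0357500), 0.94 (Os02g0765900). At 9 h the log2 fold changes become -2.52 (Os06g0697500), -1.85 (Os08g0150700), -1.05 (Os12g0160500), -1.21 (Os03g0267500), -2.08 (Os10g0344000), 1.49 (Os03g0432100), 1 (Os01g0795000), 0.92 (Os08g0109400), 1.58 (Os04g0652400), 0.81 (Os07g0568700), 0.18 (Os07g0158500), 0.37 (Os08g0196700), 0.62 (Os10g0397900), -0.01 (Os03g0411100), 0.09 (Os07g0608200), 0.12 (Os12g0613000), -0.82 (Os03g0696300), -0.28 (Os02g0776400), 0.06 (Os03g0103000), 0.07 (Os10g0110800), 0.14 (Os10g0111300), 0.73 (Os08g0155400), 0.30 (Os03g0235900), 0.12 (Os10g0370700), 0.77 (Os04g0480200), 0.65 (Os10g0554200), -0.57 (Os06g0581000), -0.30 (Os03g0687000), 0.20 (Os01g0704100), 0.96 (Os08g0468100), 0.48 (Os08g0468700), 2.07 (Os02g0770800), 0.78 (Os03g0223400), -0.21 (Os10g0456500), 0.20 (Os04g0659100), -0.13 (Os02g0735200), 0.48 (Os01g0357100), 0.57 (Os01g0357500), 0.49 (Os02g0765900).

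Directions of genes that did not pass the threshold also turned when 1 library was left out; the cause was not tested. The lowest and highest log2 fold changes over the left-out libraries were, at 3 h, -0.35 and 0.26 for Os08g0196700, -0.88 and 0.43 for Os10g0397900, -0.06 and 0.38 for Os03g0411100, -0.31 and 0.24 for Os07g0608200, -0.21 and 0.16 for Os03g0103000, -0.68 and 0.33 for Os10g0111300, -0.34 and 0.76 for Os03g0235900, -0.47 and 0.36 for Os10g0370700, -1.49 and 0.58 for Os04g0480200, 0 and 0.90 for Os03g0687000, -2.3 and 0.04 for Os02g0770800, -0.02 and 0.39 for Os10g0456500, -0.51 and 0.05 for Os04g0659100, -0.54 and 1 for Os02g0735200, and at 9 h, -0.45 and 0.08 for Os07g0158500, -2.37 and 1.77 for Os08g0196700, -0.33 and 0.48 for Os03g0411100, -0.31 and 0.13 for Os07g0608200, -0.42 and 0.15 for Os12g0613000, -0.54 and 0.35 for Os03g0103000, -0.20 and 0.10 for Os10g0110800, -0.35 and 0.14 for Os10g0111300, -1.23 and 0.11 for Os08g0155400, -0.51 and 0.40 for Os10g0370700, -0.28 and 1.42 for Os06g0581000, -0.48 and 0.07 for Os01g0704100, -0.54 and 0.10 for Os04g0659100, -0.02 and 0.31 for Os02g0735200. The peroxidase and glutathione transferase list at 3 h turned without replicate 1 of mock at 3 h, with adjusted p from 0.00156 to 0.979 over the left-out libraries. Near-zero values also turned: 0.02 for Os08g0196700 at 3 h with limma on TPM, 0.05 for Os07g0608200 at 3 h with limma on TPM, 0 for Os07g0608200 at 3 h with only the 4 libraries compared, 0.04 for Os03g0103000 at 3 h with limma on TPM, 0.01 for Os10g0370700 at 3 h with limma on TPM.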

Other observations

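Genes of diterpenoid phytoalexin synthesis, antimicrobial compounds that rice makes when attacked, were higher in replicate 2 than in replicate 1 in all 4 groups. The median log2 difference over the 8 genes was 5.11 in DEX at 3 h, 1.68 in DEX at 9 h, 2.17 in mock at 3 h and 3.4 in mock at 9 h, and 8 of 8 genes were higher in replicate 2 in each group. Syn-pimara-7,15-diene synthase, Os04g0179700 (chromosome 4, 5428347 to 5434023), stood at 1.5 and 55.2 CPM in the replicates of DEX at 3 h and at 4.46 and 38.4 CPM in those of mock at 9 h. Syn-copalyl diphosphate synthase, Os04g0178300, also on chromosome 4, stood at 0.851 and 138 CPM and at 26.0 and 281 CPM. Jasmonate synthesis and JAZ genes had medians of 0.83, 0.53, 0.56 and 0.7 in the same order of groups.

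Of the tests in this part, only the correlation of the 9 h replicate difference with the change over time was written down before its result was seen, and all others were chosen afterwards. For the phytoalexin genes, replicate 2 had the larger total count in 1 of 4 groups. CPM are already scaled for total count, so this test can say little about library size, and no conclusion is drawn from it. A wider defence response may be part of the same difference between replicates: the defence protein list, which holds other genes, had medians of 1.25, 1.27, 0.99 and 0.64 and lay above the 95th percentile of random lists in 4 of 4 groups. The design names no biological difference between replicate numbers.

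For some clock genes the difference between replicates changed with time. Among 21 genes whose replicate difference changed between 3 h and 9 h, 2 were among the 13 clock genes tested without members matched by chance (one-sided Fisher exact p = 5.06e-05): Os09g0532400, a pseudo-response regulator at 551 and 236 CPM in mock at 3 h and 13.4 and 99.9 CPM in mock at 9 h, and the FKF1-like gene Os11g0547000. The other 11 had adjusted p from 0.0524 to 0.827, and this test was chosen after the pattern was seen, so its p cannot serve as evidence. Harvest of the replicates at different times of day may account for this and stays open. A more specific form, that replicate 2 was harvested earlier in the day at 9 h, was given a bound beforehand: the replicate difference in mock at 9 h should correlate below -0.1 across genes with the change from 3 h to 9 h in the DEX libraries. The correlation was -0.097, so the prediction was missed, by less than the spread of r (SE 0.0062 if genes were independent, which they are not; computed afterwards), and the order of harvest stays open. The replicate difference in mock at 3 h, for which no prediction was written, gave -0.123.

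Over both times, 11 of the 55 described genes that rose with DEX (20%) were glutathione transferases, glycosyltransferases, cytochrome P450 or MATE transporter genes, against 2.82% of described genes tested, with a one-sided Fisher exact p of 3.12e-07. These families were picked after the called genes had been seen, so this p cannot serve as evidence, and a detoxification response to the steroid is only a candidate explanation. That candidate also rests on the column names. With the names exchanged, the 11 genes would fall and 2 other described genes of these families would rise. A further hypothesis was that the NF-YA gene with the highest count, Os07g0158500, carries reads from a transgene that holds only the coding region, which would cover inner exons more than the outer ones. The ratio lay above the 95th percentile in 5 of 8 libraries (percentiles 92.9 to 95.7), which did not meet the criterion of all 8. The reference was 2437 to 3590 multi-exon genes of high coverage per library. These were not matched to Os07g0158500 in expression or exon number, though the criterion had named such genes.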
